A study of Mus musculus with 2 samples.

How the data were processed

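Total RNA-seq libraries from hippocampal tissue of female 5xFAD/CAST mice were analysed as 1 group of 2 biological replicates, numbered as in the labels. The labels give each replicate its own biosample record and the same donor record. Whether the RNA came from separate animals is therefore not settled by them, and every SD measures the spread between these 2 samples. No control group was analysed here. Per the labels, each library was made from 300 ng of RNA with an ERCC mix for stranded, ribosomal-RNA-reduced libraries, and a directional library kit is named in the protocol.

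Per the file headers and the accompanying readme, values were made on mm10 with GENCODE M21, separately for each library. The authors deposited expected counts, TPM and a posterior SD of the count per gene and per transcript, in the column layout of RSEM, made from reads aligned to the transcriptome. The authors also deposited estimated counts and TPM per transcript in the layout of kallisto, made from reads and an index. The aligner, the counting programs and their versions are not given in the sources used here. The names RSEM and kallisto in the text refer to these layouts. TPM in the deposited gene table sums over spike-ins as well as mouse genes. Expected counts split reads that match several genes, which makes the counts of near-identical copies uncertain, and total RNA counted on transcripts leaves intronic reads out. All 55536 mouse gene identifiers matched the GENCODE M21 annotation, from which symbols, classes, coordinates and coding lengths were taken. Each gene table also holds 96 ERCC rows, 1 phiX174 row and 26248 rows with numeric identifiers and no gene name. These stayed out of library sizes and gene statistics.

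Replicates 1 and 2 held about 27816800 and 32316700 expected counts, of which 27683000 and 32169900 lay on mouse genes. A count of 0 allows up to 3 counts, or 0.108 and 0.0933 CPM, the count scaled to a common library size. Reads carry no molecular identifiers, so such floors cover counting error only. At this depth genes with fewer than 100 counts vary mainly by counting error, which is why single genes were ranked only above that count.

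Levels are the mean and SD over 2 libraries of the deposited TPM. A gene was called detected at a TPM of at least 1 in both. For ratios, expected counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16 (R 4.3.3). The log2 ratio of replicate 2 over replicate 1 used CPM with a prior count of 2, among genes with a mean count of at least 10. Where single genes were ranked, a mean TPM of at least 1 and a mean count of at least 100 were required, and a difference was called at 2-fold. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept alone, and no hypothesis test was run on single genes. Every SD is over n = 2 libraries. For each list of genes the median log2 ratio was placed among 10000 random lists of the same size drawn within 20 bins of mean expression. Kallisto TPM and counts were summed to genes. The ratio of kallisto to gene-table counts was centred on its median over nuclear protein-coding genes with a mean TPM of at least 10. Spike-ins were set beside the 20 genes nearest in count to each. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. No batch is given in the labels.

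The 43 gene lists, the settings tried and the rule for named genes were fixed before the data were examined. Named genes are the 10 nuclear protein-coding and 5 other genes with the highest TPM, the 10 highest and 10 lowest ratios between replicates, the 4 highest members of each list and its member with the largest ratio at 100 counts or more, all members of the lists on amyloid precursor processing, both microglial states, reactive astrocytes, immediate early and Y-linked genes, Xist, and the 20 isoform genes. Genes named outside this rule are marked as such. Some genes that the rule names are not reported here. One older symbol of a list was matched to its newer symbol.

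The statistics were tested on simulated counts for the same genes, with 200 genes changed. Of 18900 simulated genes past the filter, 100 were changed by 1.5 and 100 by 3 on the log2 scale. The 2-fold call found 99.0% and 100% of these, and 0% of 12884 unchanged genes with at least 100 counts. A coefficient of variation simulated at 10% was estimated at 10.0%. Of 200 random lists 6.00% lay outside percentiles 2.5 to 97.5, and all of 50 lists shifted by -0.5 lay below percentile 2.5. Simulated counts varied independently between genes and held no uncertain read assignment. The rates therefore do not cover errors from shared reads, lists whose genes vary together, or shifts smaller than those simulated.

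Alternatives covered DESeq2 1.42.0 size factors, library size alone and spike-in scaling in place of TMM, other count and TPM filters, other pseudocounts, TPM without mitochondrial genes and spike-ins, kallisto values, the mean in place of the median, other dispersion estimates, and each replicate alone.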

Results

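Total RNA from tissue labelled as layer of hippocampus, from female 5xFAD/CAST mice aged 8 to 10 months, was sequenced as 2 biological replicates. Both carry the same donor record in the labels, so whether they came from separate animals is not settled. 5xFAD mice carry human transgenes, APP among them, with familial Alzheimer mutations, driven by the Thy1 promoter, and deposit amyloid in the brain. CAST is a wild-derived inbred strain. Each library was made from 300 ng of RNA with ERCC spike-in RNAs added. The 2 libraries form 1 group with no control group beside it, so the data give the level of each gene, its spread between the 2 replicates, and the differences between the replicates. Replicates 1 and 2 held about 27816800 and 32316700 expected counts. Levels are length-scaled transcript abundances (TPM) from the gene table, as the mean ± SD over n = 2 libraries. Coordinates are those of mm10 with the GENCODE M21 annotation. No CAST sequence was used, so levels of genes whose sequence differs in CAST may be too low, which was not tested.

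In all, 15383 of 55536 mouse genes had a TPM of at least 1 in both libraries, 13251 of them nuclear protein-coding genes and 302 long intergenic noncoding RNAs. Nuclear protein-coding genes took 79.1% ± 0.868 of the expected counts on mouse genes and 45.1% ± 0.960 of the TPM. Mitochondrial ribosomal RNA took 6.49% ± 0.487 and the 13 mitochondrial protein-coding genes 2.10% ± 0.0624. Short structural RNAs led the TPM scale, which divides by length. The 7SL RNA copies Rn7s1 and Rn7s2, which form the RNA of the signal recognition particle, lie on chromosome 12 at positions 69159295 to 69159594 and 69361182 to 69361481. Each was listed at 132308 ± 210.2 TPM, and the split of reads between the copies is uncertain. Rn7sk, the RNA that holds the elongation factor P-TEFb, stood at 65283 ± 206 TPM, mt-Rnr2 at 43269 ± 2571 TPM and mt-Rnr1 at 32979.9 ± 2245 TPM. The 10 genes with the highest TPM, which include these 5, took 45.1% ± 0.497 of all mouse TPM but 15.3% ± 0.566 of the counts.

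Thy1, a surface glycoprotein of neurons whose promoter drives the 5xFAD transgenes, was the highest nuclear protein-coding gene at 2579.8 ± 96.0 TPM (chromosome 9, 44043384 to 44048579, plus strand). Of this level 1406 TPM lay on Thy1-203, a noncoding transcript of 449 nucleotides, and 1153 TPM on the coding Thy1-201. The rank of Thy1 thus rests in part on a short noncoding transcript, whose exons lie within an untranslated region of Thy1-201. No transgene sequence was used, so whether transgene RNA adds reads to Thy1 was not tested. Cst3, a secreted cysteine protease inhibitor, followed at 1970.0 ± 0.552 TPM, and the lipid carrier Apoe at 1965 ± 63.6 TPM (chromosome 7, 19696109 to 19699188, minus strand). The ferritin heavy chain Fth1 stood at 1922 ± 109.9 TPM, the elongation factor Eef1a1 at 1582 ± 52.7 TPM and Actb at 1465 ± 54.5 TPM. The other 4 of the 10 highest were Cpe, a prohormone-processing enzyme, at 1250.2 ± 7.96 TPM, Camk2a at 1234 ± 84.3 TPM, Gfap at 1148 ± 4.40 TPM and Aldoa at 1127 ± 63.7 TPM. Of the mitochondrial transcripts, mt-Co1 reached 6689 ± 70.0 TPM, mt-Co3 3988 ± 348 TPM, mt-Cytb 3769 ± 96.5 TPM and mt-Nd1 3424 ± 58.5 TPM. The count of mt-Co2 carried a posterior SD, the deposited measure of uncertain read assignment, of 3788 on 3759 counts in replicate 1, and the gene stood at 395 ± 95.4 TPM in the gene table against 1398 ± 383 TPM in the kallisto-layout table.

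Neuronal genes were abundant. All 10 pan-neuronal genes had a TPM of at least 1 in both libraries, with a list median of 167 ± 11.9 TPM. Snap25, a SNARE protein of synaptic vesicle fusion, stood at 877 ± 63.1 TPM, the dendritic protein Map2 at 437 ± 8.79 TPM, Eno2 at 419 ± 24.2 TPM and Syt1 at 381 ± 24.8 TPM. The 8 glutamatergic genes had a median of 175 ± 13.6 TPM, led by Camk2a, then Nrgn at 532 ± 49.0 TPM, the vesicular glutamate transporter Slc17a7 at 476 ± 51.4 TPM and Cck at 238 ± 20.9 TPM. The 10 GABAergic interneuron genes had a median of 36.1 ± 0.661 TPM, with the neuropeptide Sst at 149.8 ± 16.6 TPM and the GABA-synthesising enzyme Gad1 at 125 ± 1.94 TPM. Among 13 synapse genes the median was 171 ± 12.9 TPM, with the vesicle proteins Syp at 718 ± 69.2 TPM and Vamp2 at 392 ± 21.97 TPM and the postsynaptic scaffold Dlg4 at 312 ± 13.1 TPM.

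Markers of each hippocampal subfield were present. The 8 CA1 genes had a median of 29.3 ± 3.53 TPM, with Mpped1 at 70.8 ± 6.09 TPM and Wfs1 at 59.7 ± 3.09 TPM. The 10 genes of CA2 and CA3 had a median of 21.4 ± 1.41 TPM, with Cpne4 at 47.9 ± 1.17 TPM and Rgs14 at 39.6 ± 4.82 TPM. The 10 dentate granule genes had a median of 12.7 ± 0.293 TPM, with Fam163b at 46.2 ± 3.61 TPM, C1ql2 at 26.8 ± 1.25 TPM and the transcription factor Prox1 at 26.7 ± 0.905 TPM. Of 10 genes of the neurogenic lineage, 5 had a TPM of at least 1 in both libraries. Among these, Calb2 stood at 18.5 ± 2.20 TPM, and Dcx, a microtubule protein of immature neurons, at 5.58 ± 0.106 TPM. Genes chosen as markers of neighbouring regions were also detected, though some of them are used in the hippocampus too. The 8 neocortex genes had a median of 16.8 ± 1.11 TPM, with Tshz2 highest at 32.6 ± 0.898 TPM. The 8 striatum genes had a median of 4.71 ± 0.286 TPM, with Ppp1r1b at 23.7 ± 0.955 TPM. The 8 thalamus genes had a median of 5.20 ± 1.90 TPM.

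Microglial genes of the amyloid-associated state were expressed beside genes of the homeostatic state. All 22 disease-associated microglia genes and all 10 homeostatic genes had a TPM of at least 1 in both libraries, with list medians of 33.2 ± 3.17 and 26.0 ± 1.41 TPM. Trem2, the lipid-sensing receptor, stood at 86.6 ± 2.56 TPM (chromosome 17, 48346401 to 48354147, plus strand), its adaptor Tyrobp at 242 ± 13.9 TPM and the cystatin Cst7 at 77.3 ± 1.88 TPM. The integrin Itgax reached 13.04 ± 0.495 TPM, the lectin receptor Clec7a 9.68 ± 1.81 TPM, Gpnmb 30.3 ± 1.18 TPM, Lpl 27.9 ± 4.03 TPM and Spp1 9.23 ± 1.72 TPM. Among other members, the cathepsin genes Ctsd and Ctsb stood at 863 ± 7.90 and 347 ± 1.91 TPM and Cd68 at 46.3 ± 4.59 TPM. Of the homeostatic genes, the chemokine receptor Cx3cr1 stood at 49.8 ± 3.44 TPM, the purinergic receptor P2ry12 at 41.2 ± 5.47 TPM, Selplg at 40.8 ± 4.86 TPM, Siglech at 27.7 ± 1.94 TPM and Tmem119 at 18.5 ± 1.22 TPM. The summed TPM of the disease-associated list was 14.9 ± 0.0339 times that of the homeostatic list. That ratio sets 22 genes against 10, and it rests on a few abundant genes that other cells express too, Apoe and Ctsd among them. It was 9.46 ± 0.0387 without the highest gene of each list, and the ratio of the list medians was 1.28 ± 0.191.

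**Figure D1:**
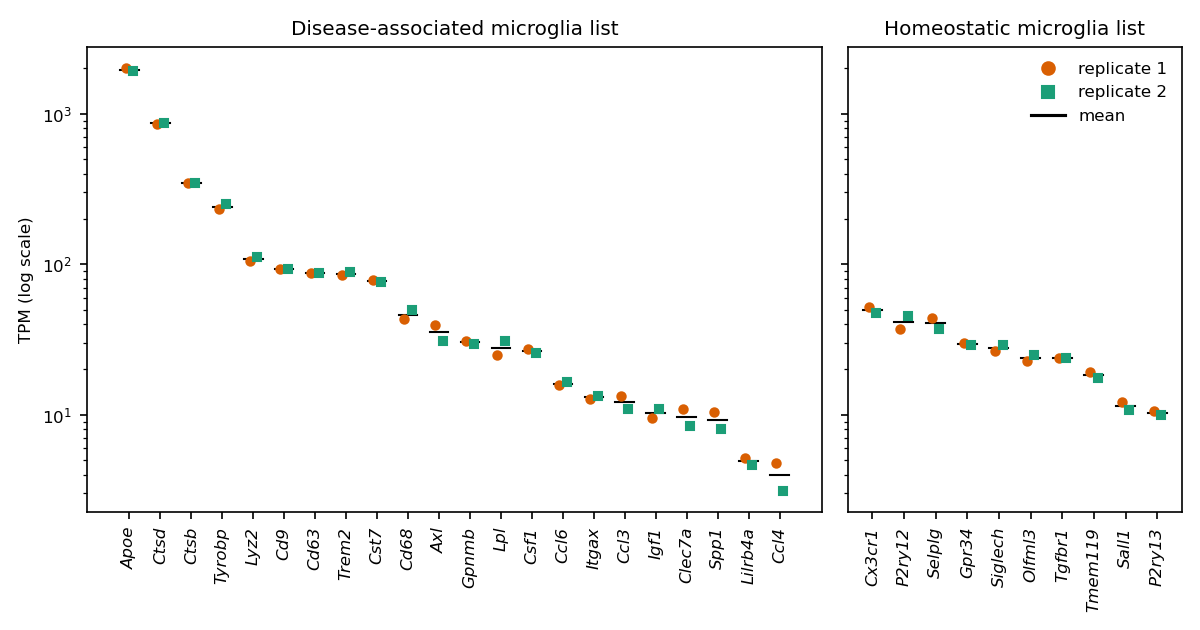
TPM on a log scale of the 22 disease-associated (left) and 10 homeostatic (right) microglia genes in replicate 1 (circles) and replicate 2 (squares), with the mean as a line. Cst7 at 77.3 TPM and Trem2 at 86.6 TPM lie above the highest homeostatic gene, Cx3cr1 at 49.8 TPM, while Itgax, Clec7a and Spp1 lie among the lowest genes of both lists.

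The 10 pan-microglial genes had a median of 118 ± 6.93 TPM, with the protease Ctss at 273 ± 18.7 TPM and the complement genes C1qa and C1qb at 158 ± 12.4 and 146 ± 16.8 TPM. Of 12 further complement genes 9 had a TPM of at least 1 in both libraries, with C4b at 185 ± 17.7 TPM and C3 at 10.3 ± 2.79 TPM. C4a, at 32.025 ± 3.37 TPM, is a near copy of C4b. Among 14 interferon-stimulated genes, 12 had a TPM of at least 1 in both libraries and the median was 3.55 ± 1.06 TPM, with Ifi27 highest at 80.1 ± 3.54 TPM. The 10 antigen presentation genes had a median of 27.6 ± 3.92 TPM, with B2m at 234.5 ± 10.8 TPM and the invariant chain Cd74 at 59.9 ± 21.5 TPM. Of 10 inflammatory cytokine genes 4 had a TPM of at least 1 in both libraries, led by Il18 at 12.045 ± 0.516 TPM and Tgfb1 at 11.4 ± 0.304 TPM. Cxcl10 stood at 2.54 ± 0.962 TPM. None of the 10 lymphocyte and neutrophil genes reached a TPM of 1 in both libraries. Trbc2, the highest, stood at 0.440 ± 0.438 TPM and S100a8 at 0.190 ± 0.0990 TPM. Of 8 perivascular macrophage genes 5 had a TPM of at least 1 in both libraries, with Stab1 at 8.74 ± 1.38 TPM and Mrc1 at 1.79 ± 0.0990 TPM.

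Astrocyte genes were abundant, with a median of 84.6 ± 3.95 TPM over 10 genes. The glutamate transporter Slc1a2 stood at 824 ± 17.3 TPM and Aldoc at 474 ± 32.7 TPM. The reactive astrocyte list was uneven: Gfap, the intermediate filament of astrocytes, stood at 1148 ± 4.40 TPM (chromosome 11, 102887336 to 102900912, minus strand), Serpina3n at 119 ± 6.80 TPM and Vim at 83.2 ± 2.80 TPM, while the other 9 genes did not exceed 10.3 TPM. Osmr stood at 7.74 ± 0.629 TPM, Cd44 at 8.35 ± 0.622 TPM and Aspg at 9.34 ± 1.69 TPM. Lcn2, an iron-scavenging lipocalin, was at 2.23 ± 1.91 TPM and Steap4 at 0.185 ± 0.00707 TPM. The 12 oligodendrocyte genes had a median of 62.9 ± 11.1 TPM, with the myelin genes Mbp at 865 ± 123 TPM and Mobp at 252 ± 59.3 TPM. The 10 precursor genes had a median of 9.24 ± 0.152 TPM, with Tnr at 53.7 ± 1.51 TPM and Pdgfra at 20.5 ± 0.877 TPM.

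Vascular and border cells gave lower levels. The 10 endothelial genes had a median of 14.1 ± 0.619 TPM, with the glucose transporter Slc2a1 at 41.5 ± 1.46 TPM and the tight-junction gene Cldn5 at 14.8 ± 0.587 TPM. The 9 mural genes had a median of 6.60 ± 0.368 TPM, with Vtn at 37.6 ± 0.559 TPM and Acta2 at 7.64 ± 0.530 TPM. The 9 fibroblast and meninges genes had a median of 3.46 ± 0.00707 TPM, although Ptgds, which oligodendrocytes also express, reached 710.1 ± 78.9 TPM. Choroid plexus genes had a median of 2.11 ± 1.70 TPM over 12 genes, ependymal genes 2.61 ± 1.84 TPM over 8, and red blood cell genes 37.6 ± 8.91 TPM over 6. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at most 1 expected count per library, although Uty was listed at a mean of 1.42 TPM in the kallisto-layout table. Eif2s3y had 0 counts in both, which allows up to 3 counts, or 0.108 and 0.0933 CPM (counts scaled to a common library size) in replicates 1 and 2. Floors of this kind cover counting error only. Xist, the RNA of the inactive X chromosome, stood at 86.4 ± 4.33 TPM (chromosome X, 103460366 to 103483254, minus strand).

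Genes of amyloid precursor processing were all detected. App stood at 519.6 ± 28.3 TPM in the gene table (chromosome 16, 84949685 to 85173766, minus strand), Aplp1 at 534 ± 19.1 TPM and Aplp2 at 209 ± 1.61 TPM. The beta-secretase Bace1 reached 31.6 ± 0.148 TPM and the alpha-secretase Adam10 29.4 ± 1.59 TPM. Of the gamma-secretase genes, Psen2 stood at 9.51 TPM in both libraries, Ncstn at 30.9 ± 1.32 TPM and Psenen at 40.1 ± 2.57 TPM. The amyloid-degrading protease Ide stood at 16.2 ± 0.707 TPM and Mme at 1.29 ± 0.113 TPM, and tau (Mapt) at 132 ± 0.431 TPM. In the kallisto-layout table App stood at 1032 ± 34.2 TPM, 1.99 times its gene-table level. Psen2 stood at 9.90 TPM there. Of 20 mouse orthologues of Alzheimer risk genes, 18 had a TPM of at least 1 in both libraries. Clu, a chaperone of the apolipoprotein class, stood at 770.2 ± 48.9 TPM, the kinase Ptk2b at 281 ± 22.2 TPM, Bin1 at 125 ± 1.77 TPM, Picalm at 73.9 ± 1.02 TPM, Spi1 at 8.67 ± 1.56 TPM and Cd33 at 7.93 ± 0.707 TPM.

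**Figure D2:**
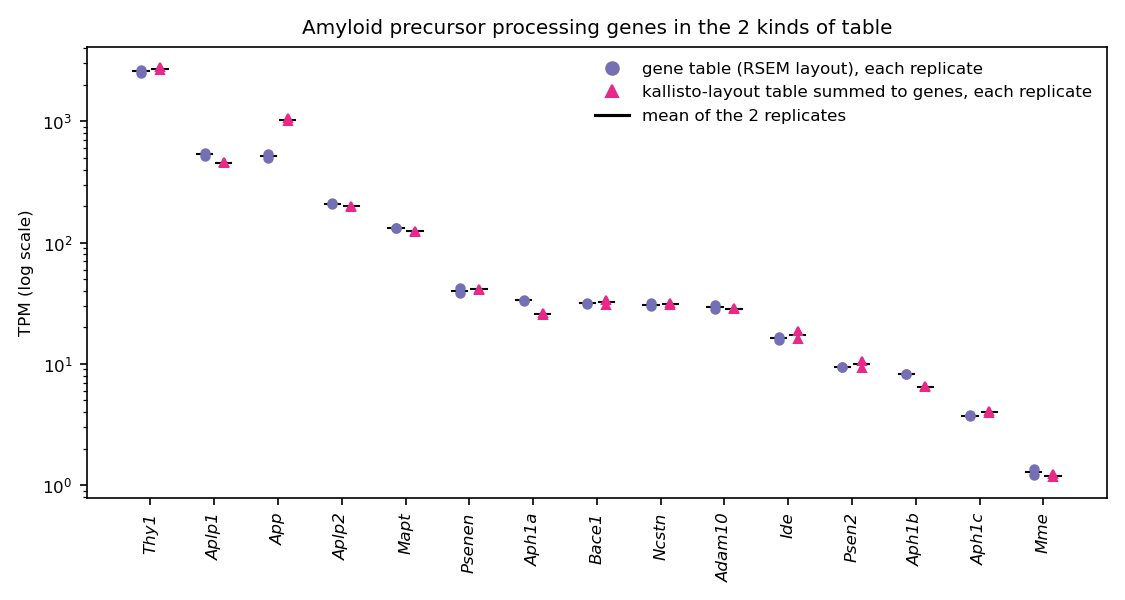
TPM on a log scale of 15 amyloid precursor processing genes in each replicate, from the gene table in the RSEM layout (circles) and the kallisto-layout table summed to genes (triangles), with means as lines. Of the genes drawn, App at 519.6 against 1032 TPM differs most between the 2 kinds of table.

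All 16 immediate early genes had a TPM of at least 1 in both libraries, with a median of 14.8 ± 1.33 TPM. Arc stood at 39.2 ± 1.05 TPM, Junb at 32.02 ± 0.424 TPM, Egr1 at 24.6 ± 0.679 TPM, Fos at 10.4 ± 0.587 TPM and Npas4 at 3.33 ± 0.658 TPM. The 15 circadian genes had a median of 30.4 ± 0.283 TPM, with the output factors Tef at 95.8 ± 5.61 TPM and Dbp at 51.5 ± 1.57 TPM. Per1 stood at 46.5 ± 0.792 TPM in the gene table and 30.9 ± 1.34 TPM in the kallisto-layout table. The 9 glucocorticoid response genes had a median of 17.6 ± 0.721 TPM, with Sgk1 at 75.0 ± 6.34 TPM and Fkbp5 at 34.2 ± 1.82 TPM. The 10 heat shock genes had a median of 29.0 ± 3.67 TPM, led by the chaperones Hspa8 at 794 ± 51.6 TPM and Hsp90aa1 at 413 ± 13.9 TPM. Cholesterol synthesis genes had a median of 32.5 ± 1.98 TPM over 15 genes, with Hmgcs1 at 116 ± 9.33 TPM. The 12 nuclear genes of oxidative phosphorylation had a median of 158 ± 0.824 TPM, with Atp5b at 689.9 ± 39.1 TPM, against 2487 ± 61.4 TPM for the 13 mitochondrially encoded genes. The 12 cytosolic ribosomal protein genes had a median of 264 ± 14.2 TPM, with Rplp1 highest at 765 ± 37.1 TPM. Among 12 long noncoding RNAs the nuclear RNA Malat1 stood at 5190.3 ± 587 TPM, and at 2821 ± 277 TPM in the kallisto-layout table, and Meg3 at 1034 ± 69.0 TPM. The 13 imprinted genes had a median of 15.3 ± 1.24 TPM, with Snrpn at 329 ± 13.9 TPM and Nnat at 232 ± 16.6 TPM.

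The next comparison was between the replicates. Across 28146 genes with a TPM above 0 in either library, log2(TPM + 1) of the replicates had a Pearson r of 0.990 and a Spearman rho of 0.952. These correlations are across genes, which are not independent replicates. Among 18897 genes with a mean expected count of at least 10 the median absolute log2 ratio was 0.12, and without the count filter it was 0.19. The biological coefficient of variation, edgeR's estimate of the spread between replicates beyond counting noise, was 7.11%. ERCC spike-ins took 0.467% ± 0.0190 of the expected counts and 0.856% of the TPM, and 63 of 96 had counts in both libraries. For 43 spike-ins with a mean count of at least 10 the median absolute log2 ratio was 0.17, against 0.15 for 772 mouse genes matched on count. At a mean count of at least 100 these values were 0.09 for 25 spike-ins and 0.10 for 452 genes. Under this scaling the spike-ins shared an offset, with a median log2 ratio of -0.069. The median absolute deviation from the median leaves that offset out. It was 0.151 for spike-ins and 0.147 for genes at 10 counts, and 0.071 and 0.103 at 100 counts.

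Some gene groups differed between the replicates by more than random lists of genes did. For each list with at least 4 members at a mean count of 10 or more, the median log2 ratio of replicate 2 over replicate 1 was set against 10000 random lists of the same size matched on expression. Of 41 lists tested, 17 medians lay in the lowest 2.5% of the random medians and 4 in the highest 2.5%, where about 2.05 would lie outside by chance if the genes of a list varied independently. Genes of a list are expressed together, so these percentiles describe these libraries and are no test between conditions. Members are called lower or higher by this ratio of scaled counts, and in TPM some lay on the other side. Lef1 of the thalamus list, outside the naming rule, had a log2 ratio of -0.24. Its TPM was 3.74 in replicate 1 and 4.75 in replicate 2. The astrocyte gene Slc1a2 stood at 811 and 836 TPM. Dhcr7 of the cholesterol list, also outside the rule, stood at 21.1 and 18.5 TPM.

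Choroid plexus genes stood furthest apart. All 12 were lower in replicate 2, with a median log2 ratio of -1.35, below all 10000 random lists. Ttr, the thyroxine carrier made by the choroid plexus, stood at 426 TPM in replicate 1 and 146 TPM in replicate 2, a log2 ratio of -1.56 (chromosome 18, 20665280 to 20674321, plus strand). The chloride channel gene Clic6 had a log2 ratio of -1.56, Kcnj13 -0.84, Sostdc1 -0.82 and Kl -0.58. All 8 ependymal genes were lower as well, with a median of -1.16. The cilia regulator Foxj1 had a log2 ratio of -1.11 and Ccdc153 -1.33, while Rsph1 and Rarres2 were at -0.18 and -0.10. All 8 thalamus genes were lower in replicate 2 in scaled counts, with a median of -0.81. The transcription factor Tcf7l2 had a log2 ratio of -1.24, the kinase Prkcd -1.12, Synpo2 -0.97 and the vesicular glutamate transporter Slc17a6 -0.61. The 5 red blood cell genes tested had a median of -0.53, with Hba-a1 at -0.56 and Hbb-bs at -0.53. Haemoglobin genes are near copies of each other, and Hba-a2 stood at 66.1 ± 17.3 TPM in the gene table and 34.4 ± 7.63 TPM in the kallisto-layout table.

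Glial and immune lists were shifted the same way by smaller amounts. All 12 oligodendrocyte genes were lower in replicate 2, with a median of -0.34, Mbp at -0.32, Mobp at -0.50 and Aspa at -0.56. The 10 precursor genes had a median of -0.05 at percentile 6.75, which spike-in scaling turned to 0.02. All 10 antigen presentation genes were lower, with a median of -0.41, H2-Eb1 at -1.08, Cd74 at -0.76 and B2m at -0.11. Of 14 interferon-stimulated genes 12 were lower, with a median of -0.25 and Ifit3b at -0.82. All 10 astrocyte genes were lower by small amounts, with a median of -0.11, and 9 of 10 pan-microglial genes, with a median of -0.16 and Aif1 at -0.44. The median was -0.16 for 12 reactive astrocyte genes, with C3 at -0.67 and Lcn2 at -1.90 on few counts, -0.08 for 10 homeostatic microglia genes, -0.17 for 11 complement genes, -0.24 for 9 fibroblast and meninges genes and -0.05 for 19 Alzheimer risk orthologues, with Spi1 at -0.60. Each of these 5 lists lay below percentile 2.5 and moved inside it in 2 or 3 of 5 alternatives. With log2(TPM + 0.1) the fibroblast and meninges median was -0.02 at percentile 32.6, the reactive astrocyte median -0.09 at percentile 4.80, the homeostatic median -0.05 at percentile 4.87 and the Alzheimer risk median -0.02 at percentile 6.46. In kallisto counts the fibroblast and meninges median was -0.11 at percentile 7.13. The complement list lay at percentile 15.3 by the mean over its genes, and its median was -0.11 at percentile 8.11 with no low-count filter. Disease-associated microglia genes had a median of -0.02 at percentile 4.98, with 14 of 22 lower, and spike-in scaling turned the median to 0.05. Ccl4 had a log2 ratio of -0.62 on few counts, and Lpl 0.28. Long noncoding RNAs had a median of -0.15, with Malat1 at -0.24 and Neat1 at -0.48. Glucocorticoid response genes had a median of -0.09 at percentile 2.16, with the lipid droplet gene Plin4 at -0.87. The mitochondrially encoded list had a median of -0.05 below all random lists, which the mean over its genes placed at percentile 3.70. Spike-in scaling moved the median of all genes from -0.00 to 0.07, and with it the medians of this list and of the Alzheimer risk orthologues to 0.02 each, of homeostatic microglia genes to -0.01, of glucocorticoid response genes to -0.02 and of astrocyte genes to -0.04.

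Neuronal lists lay on the other side. All 8 glutamatergic genes were higher in replicate 2, with a median of 0.17 and Neurod2 at 0.25. The 8 CA1 genes had a median of 0.13, with 7 higher and Dcn at 0.46, and the 10 pan-neuronal genes 0.12, with 9 higher and Stmn2 at 0.18. With the ratio of log2(TPM + 0.1) the pan-neuronal list moved inside the bounds, to percentile 89.99. All 15 cholesterol synthesis genes were higher, with a median of 0.11 and Nsdhl at 0.22. Dentate granule genes had a median of 0.09 at percentile 97.2, GABAergic genes 0.09 at percentile 95.4, cytosolic ribosomal protein genes 0.09 at percentile 97.1, nuclear oxidative phosphorylation genes 0.08 at percentile 92.3, synapse genes 0.08 at percentile 82.1 and CA2 and CA3 genes 0.04 at percentile 79.8. The amyloid precursor processing list had a median of 0.04 at percentile 67.6, and the circadian list 0.05 at percentile 79.9. Immediate early genes had a median of 0.00 at percentile 46.8, imprinted genes 0.00 at percentile 32.2, endothelial genes 0.03 at percentile 73.8 and mural genes 0.07 at percentile 87.5. Also inside the bounds were the neocortex list at -0.07, the striatum list at -0.10, the neurogenic lineage at -0.02, heat shock genes at -0.01, perivascular macrophage genes at -0.25 and inflammatory cytokine genes at -0.15. Spike-in scaling turned the neocortex, neurogenic and heat shock medians to 0.01, 0.05 and 0.06. The lymphocyte and neutrophil and the Y-linked lists had too few counted members.

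**Figure D3:**
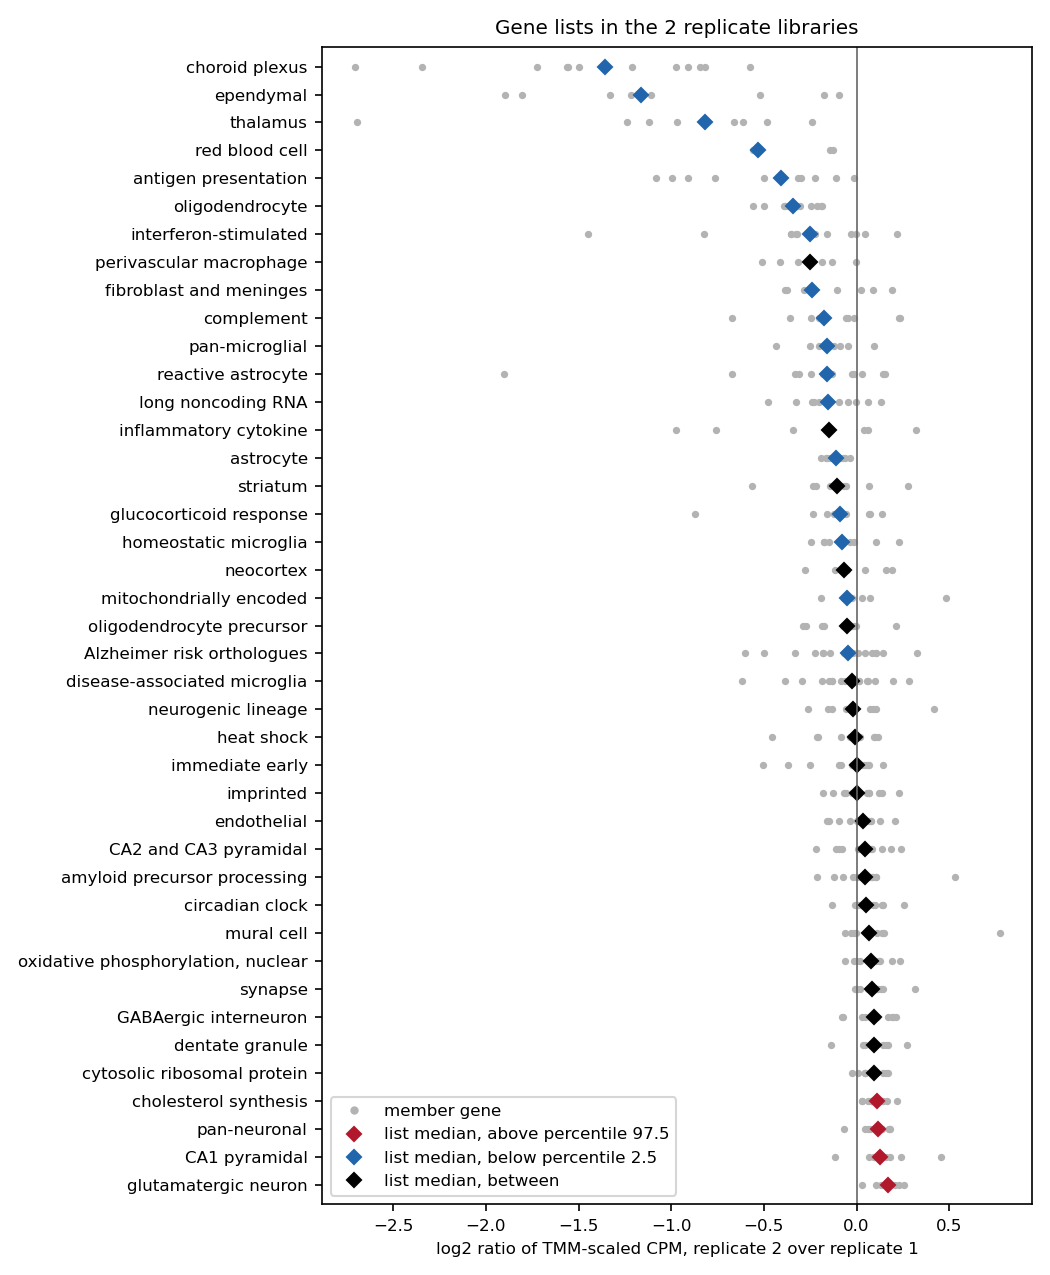
Log2 ratio of TMM-scaled CPM, replicate 2 over replicate 1, for each member (grey points) and the median (diamonds) of the 41 lists tested. Diamonds are coloured where the median lies in the lowest 2.5% (17 lists) or the highest 2.5% (4 lists) of matched random lists. The choroid plexus, ependymal and thalamus medians, -1.35, -1.16 and -0.81, lie farthest from 0.

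Single genes with large differences between the replicates were few. Of 13062 genes with a mean TPM of at least 1 and a mean count of at least 100, 22 were at least 2-fold lower and 13 at least 2-fold higher in replicate 2, and 90% had an absolute log2 ratio of no more than 0.26. With a mean count of at least 10 and no TPM filter, 503 genes differed by 2-fold or more, 146 of them higher. Rpl7a-ps11, a ribosomal protein pseudogene, had 568 counts in replicate 1 and 0.04 in replicate 2. Gm12671 had 259 counts against 0. Bpifb9b had 474 counts against 0, with a posterior SD of 13.95 counts in replicate 1 and 0.31 in replicate 2, and a log2 ratio of -8.15 in kallisto counts. On the other side Gm20388, a gene model on chromosome 8 from 119910841 to 124345722, had 0 counts against 574. The pseudogenes Gm10240 and Gm13370 both had a log2 ratio of 2.32, the gene Fam220a 2.28, the second gene record named Myl12b 1.90, Tmem254b 1.63, Gm8226 1.57, Rps18-ps3 1.51, Gm12070 1.48 and Gm6344 1.40. A second gene record named Nnt stood at -2.64, Gm21887 at -1.72, Nutf2 at -1.55 and Gm15427 at -1.498. In the kallisto-layout table the log2 ratio was -4.97 for Rpl7a-ps11, -1.64 for Nnt, 4.41 for Myl12b, 1.53 for Gm20388, -0.36 for Nutf2 and -0.19 for Fam220a, and Gm12671, Gm15427 and Gm6344 were listed at a mean of 0 TPM. The posterior SD was at least 5% of the count in either library in 22 of the 35 genes, Bpifb9b among them through its count of 0 alone, and 7 of the 22 were also at least 2-fold apart in the same direction in kallisto counts. The other 13 were all lower in replicate 2, and 11 of them were also at least 2-fold lower in kallisto counts. The 11 include Ttr, Clic6, Tcf7l2, Prkcd and H2-Eb1, while Foxj1 had a log2 ratio of -0.98 there. Mfrp, a membrane frizzled-related protein, had a log2 ratio of -1.53 with a posterior SD above that limit, and -1.58 in kallisto counts.

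The 2 transcript tables of each library were compared last. Across transcripts, log2(TPM + 1) in the RSEM-layout and kallisto-layout tables had a Pearson r of 0.814 in replicate 1 and 0.820 in replicate 2, with Spearman rho values of 0.683 and 0.682. Summed to genes, r was 0.945 and 0.950. Of 10018 genes with a mean TPM of at least 5 and more than 1 transcript, 74.4% had the same leading transcript in both tables in both libraries. Between the replicates the leading transcript was the same for 89.0% of genes in the RSEM-layout table. Among 8397 nuclear protein-coding genes with a mean TPM of at least 10, 91.5% had a centred ratio of kallisto to gene-table counts within 10% of 1. App, at 2.09, ranked 11 from the highest.

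Of the 20 genes chosen for isoforms 17 had the same leading transcript in both tables; the exceptions were Gria1, Grin1 and Picalm. App-201, which codes for 695 residues and lacks the protease inhibitor domain, held 87.5% ± 1.52 of App TPM in the RSEM-layout table and 80.4% ± 2.40 in the kallisto-layout table. Reads of the human APP transgene, if counted on App, cannot be told apart from mouse App in these shares. For Mapt, Mapt-204 held 68.5% ± 1.27 and 65.2% ± 0.946. Gfap-201 held 93.6% ± 0.436 and 89.3% ± 0.481, and Trem2-201 78.9% ± 1.86 and 82.5% ± 0.916. For other genes the shares moved more between the tables. Apoe-209 held 87.4% ± 0.657 of Apoe TPM in the RSEM-layout table and 52.9% ± 0.363 in the kallisto-layout table, where Apoe-205, with the same 311 coding residues, took 35.0% ± 0.101. Mbp-211 held 70.0% ± 1.84 and 40.7% ± 1.26, and Clu-201 97.3% ± 0.268 and 79.95% ± 0.644. Grin1 was divided between Grin1-201 at 33.1% ± 0.218 and Grin1-205 at 26.6% ± 0.314 in the RSEM-layout table, and at 24.6% ± 1.48 and 25.2% ± 1.58 in the kallisto-layout table. Cd33, at low TPM, had Cd33-203 leading with 32.7% ± 0.0903 and 33.3% ± 0.719.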

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

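Some counts lay outside the comparisons above. The phiX174 entry, a sequencing control genome, had 179 expected counts in replicate 1 and 211 in replicate 2, beyond the 3 that a count of 0 allows. The 26248 entries with numeric identifiers, which carry no gene name, had 4 expected counts together in replicate 1 and 2 in replicate 2, a sum over all of them to which the limit for a single entry does not apply. No explanation of these counts was tested.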

How the results depend on the processing

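The restriction to genes with a posterior SD under 5% of the count and the random lists drawn from protein-coding genes were tests chosen after the data were seen. No paired analysis was possible because the samples form 1 group.

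The number of lists outside the random lists, 21, was 16 with log2(TPM + 0.1), 20 with kallisto counts, 16 with the mean in place of the median, 20 with no low-count filter and 21 against protein-coding genes. Of 205 list medians under 5 alternatives, 184 kept their side of the bounds, 14 called medians moved inside, 2 moved outside and 5 medians of the neurogenic, immediate early and heat shock lists, inside the bounds, changed sign. The 2 that moved outside were the GABAergic list in kallisto counts, at percentile 97.79, and the synapse list by the mean, at percentile 98.12. Outside in all 5 alternatives were 14 of the 21 lists. The genes differing by 2-fold or more numbered 35 with DESeq2 size factors, spike-in scaling or kallisto counts and 43 with log2(TPM + 0.1). Not all were the same genes: 18 of the 35 in the main setting were also at least 2-fold apart in the same direction in kallisto counts. Spike-in scaling and kallisto counts each gave 20 lower and 15 higher in replicate 2, against 22 and 13 in the main setting. Lowering the count minimum to 10 without a TPM filter gave 503, and keeping genes with a small posterior SD alone gave 13, since that choice leaves out 62.9% of the genes at 2-fold or more and 2.86% of the others. Detected genes numbered 21548 at a TPM of 0.1, 18274 at 10 counts and 15976 in kallisto TPM.

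The Pearson r between replicates was 0.969 with a pseudocount of 0.1, 0.981 at a mean TPM of at least 1 and 0.992 in kallisto TPM. The median absolute log2 ratio was 0.12 with DESeq2 size factors, 0.12 with library size alone, 0.15 with spike-in scaling, 0.19 with no filter, 0.087 at 100 counts and 0.13 in kallisto counts. The coefficient of variation was 7.12% with RLE scaling, 7.26% with no filter, 6.35% at 100 counts, 8.81% as the median of trended dispersions and 7.12% without mitochondrial and the 10 highest genes. The spike-in median absolute log2 ratio was 0.094 at 100 counts. The cause was not tested.

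The microglial ratio was 1.28 from list medians, 15.1 in kallisto TPM and 9.46 without the highest gene of each list. The median level of 473 list genes, 20.3 TPM, was 21.4 without mitochondrial genes and spike-ins in the total and 18.6 in kallisto TPM. Spike-ins took 0.856% of TPM and 0.402% of kallisto counts, and nuclear protein-coding genes 45.1% of TPM and 80.5% of kallisto counts. Between the transcript tables r was 0.716 with a pseudocount of 0.1 and 0.688 at a mean TPM of at least 1, and 0.908 and 0.884 for genes. The share of genes with the same leading transcript was 71.7% at a gene TPM of 1 and 75.6% at 20. The cause was not tested. Of 120 single-gene levels in kallisto TPM or with mitochondrial genes and spike-ins taken out of the total, which rescales every gene alike, 91 moved by more than the SD of the replicates.

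With either replicate left out, detected genes ranged from 15877 to 16259, the microglial ratio from 14.8 to 14.9, and the median level of list genes from 19.61 to 20.96 TPM. Depth limits single-gene ratios below 100 counts.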

Other observations

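The tests of scaling between the libraries, of reads shared between near-identical genes and of the App counts in the form given here were chosen after the result was seen, as was the MHC class II set.

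Among antigen presentation genes, the 4 MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had a median log2 ratio of -0.95 between the replicates, from -1.08 to -0.76, and -0.85 in kallisto counts. The 3 class I genes H2-K1, H2-D1 and B2m had a median of -0.22. Of Thy1 TPM, Thy1-203, a noncoding transcript of 449 nucleotides, held 54.5% in the RSEM-layout table and 51.2% in the kallisto-layout table, and Thy1-201 44.7% and 47.2%. The exons of Thy1-203, at positions 44047922 to 44047992 and 44048197 to 44048574 of chromosome 9, lie within an untranslated region of Thy1-201 at positions 44047449 to 44048579.

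Choroid plexus and thalamus genes were lower in replicate 2. Scaling between the libraries as the whole cause is argued against by the subfield lists, whose lowest median was 0.044, and assignment by a single program by the kallisto counts, in which the choroid plexus median was -1.30. Different amounts of neighbouring tissue in the dissections may explain both lists: second lists, written before their values were seen and sharing no gene with the fixed lists, had medians of -0.82 for 12 choroid plexus genes, 11 of them lower, and -0.52 for 9 thalamus genes, 8 of them lower, the latter close to the bound of -0.5. Their most abundant genes were Enpp2 at 115.9 ± 34.5 TPM and Rora at 18.8 ± 4.72 TPM, and 7 genes of each list had a TPM of at least 1 in both libraries, so the hippocampal samples express many of them. No biological explanation was tested, and a difference between animals stays open.

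App counts were 2.09 times higher in the kallisto-layout table than in the gene table after centring. The posterior SD of App was 0% of its count, so the gene table showed no uncertain assignment among the reads it counted on App. That value does not cover reads counted in the kallisto-layout table alone. It therefore cannot decide whether reads shared with other annotated loci added to the excess. Reads from the human APP transgene, kept in that table alone, and CAST sequence differences in App cannot be told apart as sources of the excess. The family members Aplp1 and Aplp2, which the transgenes do not carry, reached at most percentile 23.4 of the ratio and 0.131% of genes had a ratio as high as App, which either source might give. No transgene or CAST sequence was used here.

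The largest ratios of single genes between replicates may reflect reads shared between near-identical genes. A posterior SD of at least 5% of the count was found in 62.9% of the genes at 2-fold or more and in 2.86% of the others, a difference of 60.0 percentage points. This leaves open the other 13 genes, Bpifb9b, which is counted among the 22 genes through its count of 0 alone, and 7 of the 22 that were also at least 2-fold apart in kallisto counts, Bpifb9b among them. No biological explanation was tested.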
